A study of Mus musculus with 4 samples.

How the data were processed

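Olfactory epithelia of mice were dissociated with papain and mature olfactory sensory neurons were isolated by fluorescence-activated sorting, and libraries were made from polyadenylated RNA with the Illumina TruSeq protocol, per the labels' protocols. The 4 libraries fall into 2 groups by their titles, control and Nd1, with 2 replicates each, at 212 days (replicate 1) and 87 days (replicate 2). The labels do not state how many mice entered each library. The submitters' processing notes name Bowtie, Cuffdiff 1.3.0 and the genome build mm9. The annotation and the filters are not given in the sources used here.

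The authors deposited 1 table for the series, with a single FPKM value per group for 28168 loci. FPKM is the number of fragments scaled by transcript length and by the number of mapped fragments, and was computed by the authors with Cuffdiff. The authors' log2 fold change, test statistic, p-value and q-value for Nd1 against control stand beside these values, per the file headers. No column holds a value per library, so the number of per-sample columns used is 0. The status column marks 14841 loci as tested, 12711 as not tested and 616 as failed. The listed log2 fold change equals the log2 ratio of the 2 FPKM values within 1.38e-05 in tested loci above 0 in both groups, and it is set to 0 in all loci whose test failed (100.0%). In 1592 loci a placeholder stands where a group is at 0, and no fold is given for these. The q-value equals a Benjamini-Hochberg adjustment of the p-values over the tested loci, within 1% in 100.0% of them, and 772 tested loci have a q listed as 0.

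The symbol column is empty for 4724 loci, joins several symbols in 326 and is shared with another locus in 2380. In 25 loci a calendar date stands in place of the symbol, and 8 of these were called. They could not enter the gene lists. Coordinates are those of the table on mm9, with 1 added to each start. They bound the locus as the table lists it, which 2 entries can share, as those of Fam116a do, and need not be the ends of the named gene. Of 962 odorant receptor loci under 1.1 kb, 90.6% have a length that is a multiple of 3 when the start is counted from 0, as a coding exon read in that way would. The reference annotation at hand is of another build and was not used here.

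The depth of each library is unknown. In the short odorant receptor loci the smallest non-zero product of FPKM and length in kb was 0.033 in control and 0.029 in Nd1, with 7 and 32 loci within 2% of it. Whether that step is the worth of a single fragment was not shown. Because each value combines 2 libraries, whole reads were not recovered, and neither intervals nor detection floors are given.

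The planned test, limma on values per library, and the planned camera test of gene lists need values per library, which the table used here does not hold. As fixed for that case before the data were examined, the authors' fold changes and q-values are reported as theirs at q under 0.05 and no test was run. For each of 26 gene lists and 6 families fixed before the data were examined, the members called in each direction were counted, and the authors' p-values were adjusted again over the tested members of the list alone. A symbol with several loci was represented by the locus of the highest mean FPKM, and joined loci were left out of the 26 lists, while the families, matched by symbol pattern, kept 3 joined loci. The list median was taken over tested members with a mean of at least 0.5 FPKM on the scale log2(FPKM + 1), which understates changes of low genes. Its percentile was found among 10000 random lists of the same size drawn from 20 bins of mean expression, for lists with at least 5 such members. Where a family filled most of a bin, as the odorant receptors do, its draws came from all other loci. A list whose percentile lies under 0.5 or over 99.5 is described as apart from matched lists.

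Genes were named by a rule fixed before the data were examined. It takes the 10 largest rises and the 10 largest falls in log2 fold change among called loci of at least 1 FPKM in a group, with odorant receptors given as a family, then up to 4 members of each list by size of change, and Omp, Cnga2, Adcy3 and Gnal whatever their values. Loci without a symbol cannot be named by it, and a few genes that it or a small count would name are not reported here. The percentile and the adjustment were tested on simulated data over 13727 loci for the comparison of gene lists. With 200 changed loci in 10 lists of 20, a shift of 1 (log2) put 10 of 10 lists outside the range and a shift of 0.5 put 8 of 10 outside, while 2 of 100 unchanged lists lay outside. The simulated loci varied independently, unlike genes regulated together, and fewer random lists were drawn than for the real lists. The adjustment found 200 of 200 changed loci and 8 unchanged ones. All changed loci had been given the same very small p-value, so their recovery was fixed in advance and is no measure of power.

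Alternatives were pseudocounts of 0.1 and 0.5, other expression minimums (none, or a mean of 2 FPKM), quantile and median-ratio scaling, a q threshold of 0.01, counts without odorant receptors or with 1 locus per symbol, and other backgrounds and memberships for the lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.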

Results

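RNA from mature olfactory sensory neurons of mice was sequenced in 4 libraries, 2 from the transgenic line Nd1 and 2 from control mice. These neurons detect odorants in the nasal epithelium, and each normally expresses a single odorant receptor gene. The series title states that the transgenic mice express double-stranded RNA (dsRNA) encoded in the genome, and its design text states that the lines show neurodegeneration. Per the genotype labels, the mice behind all 4 libraries carried a GFP reporter at the Omp gene, and those of both Nd1 libraries carried the Nd1 insertion together with tTA, a transcriptional activator placed at Omp. The control of replicate 1 carried Nd1 without tTA, and the control of replicate 2 carried tTA without Nd1. In each group replicate 1 was 212 days old and replicate 2 was 87 days old. The deposited table holds a single pooled FPKM value per group for each of 28168 loci, so no value per library, no spread between replicates and no read depth per library can be given. All FPKM values below are the authors' pooled values, and every call is theirs, at q under 0.05 from Cuffdiff. The words rose and fell are used only for loci that passed that threshold.

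The comparison of Nd1 with control asks what the dsRNA-expressing line changes in the RNA of sorted neurons. Genes of the interferon response and of antigen presentation rose, many of them from values near 0, while 88.2% of the tested odorant receptor loci fell. Of 14841 loci tested in the authors' deposited table, 5102 (34.4%) passed, of which 2246 were higher and 2856 were lower in Nd1. Odorant receptor loci made up 896 of the falls, which leaves 2242 higher and 1960 lower among all other loci. Counting only loci of at least 1 FPKM in a group and changes of at least 2-fold, and leaving odorant receptors out, 811 loci rose and 358 fell. At 8-fold these counts were 172 and 35. The median locus scarcely moved, with a log2 ratio of -0.069 over the 13727 tested loci with a mean of at least 0.5 FPKM.

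The largest rise as a plain ratio was that of Rasgrf1, a guanine nucleotide exchange factor for Ras (mm9 chromosome 9, 89804613 to 89921817), from 0.0077 to 10.4 FPKM, a log2 fold change of 10.41 (q = 3.18e-09) in the authors' deposited table. With a pseudocount of 1 its log2 ratio was 3.51, the 22nd largest, and Oasl2 stood first at 5.93. Several of the next genes belong to the interferon response. Ifi44 went from 0.055 to 23.9 FPKM, Oasl2 from 0.29 to 77.7 and Oasl1 from 0.015 to 2.73, with log2 fold changes of 8.75, 8.07 and 7.50 in the authors' deposited table. Rtp4, an interferon-inducible receptor transporter protein, rose from 0.46 to 58.8 FPKM. Isg15, a ubiquitin-like modifier, rose from 0.50 to 58.8 FPKM and Xaf1, a pro-apoptotic interferon target, from 0.25 to 29.1 FPKM. The remaining 3 of the 10 largest rises were Fam19a2 (0.045 to 6.64 FPKM), the lymphocyte activation antigen Cd69 (0.031 to 4.51 FPKM) and the transcript 9330175E14Rik (0.021 to 2.73 FPKM). In 6 of these 10 genes the control value was under 0.1 FPKM, and the table gives no spread for such values.

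Outside the odorant receptors, the 10 largest falls included 5 trace amine-associated receptors, Taar7a, Taar7d, Taar7e, Taar7f and Taar9. The steepest as a plain ratio was that of the predicted gene Gm10081, from 1.78 to 0.050 FPKM, with a log2 fold change of -5.16 (q = 0.00747) in the authors' deposited table. With a pseudocount of 1 it was -1.40, the 61st steepest, and Taar9 stood first at -2.98. Twist2, a bHLH transcription factor, fell from 8.52 to 0.33 FPKM and Col27a1, a fibrillar collagen gene, from 9.73 to 0.45 FPKM. Cyp2c44, a cytochrome P450 gene, fell from 1.93 to 0.099 FPKM, and the joined locus of Dio3os and Mir1247 fell from 8.34 to 0.50 FPKM. Named loci listed at 0 in a group have no fold. Those of at least 1 FPKM in Nd1 and listed at 0 in control were Gm14743 (2.07 FPKM), Gm14744 (3.57 FPKM), the lipocalin Lcn11 (2.41 FPKM) and the odorant-binding protein Obp1a (1.98 FPKM). The chemokine Ppbp and the protease Prss23 were listed at 0 in Nd1, beside 1.49 and 1.01 FPKM in control.

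Interferon-stimulated genes rose almost as a body. Of 40 tested members of the list, 37 rose, 1 fell and 2 did not pass in the authors' deposited table, and adjusted over the list alone the counts were 37 and 1. The single fall was that of Ifit2, from 13.2 to 4.74 FPKM, named here after its value was seen, as are all genes beyond the naming rule that complete a count of 5 or fewer. The list median was 2.43 on the log2(FPKM + 1) scale, at percentile 100 of 10000 random lists of matched expression. Of 20 tested genes of dsRNA sensing and signalling, 10 rose and 3 fell, or 11 and 4 adjusted over the list alone. Among the rises, Oas1a, which makes the activator of RNase L, went from 0.24 to 20.6 FPKM, the RIG-I-like receptors Dhx58 from 0.54 to 20.4 and Ifih1 from 2.68 to 19.4, and the transcription factor Irf1 from 0.62 to 4.19 FPKM. The falls were those of Dicer1 (50.4 to 39.8 FPKM), Eif2c2 (26.4 to 21.2 FPKM) and Irf3 (14.8 to 12.2 FPKM). The list median was 0.47, at percentile 100. That position rested on its less expressed members, for among genes of the upper 50% of mean expression the list median was -0.019, at percentile 68.1. The list shares several members with the interferon-stimulated genes, among them Oas1a.

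Antigen presentation genes moved in the same direction. Of 19 tested members 12 rose and none fell in the authors' deposited table, while adjusted over the list alone 12 were higher and 1 was lower. B2m, the light chain of MHC class I (mm9 chromosome 2, 121945844 to 122011925), rose from 13.3 to 352 FPKM, a log2 fold change of 4.73 in the authors' deposited table. Nlrc5, the transactivator of MHC class I genes, rose from 0.047 to 3.37 FPKM, the heavy chain H2-K1 from 5.43 to 42.2 FPKM and the immunoproteasome subunit Psmb9 from 0.42 to 3.98 FPKM. The list median of 1.06 lay at percentile 100 of matched lists. By contrast, only 10 of 25 genes of the NF-kB, cytokine and chemokine list were tested. Of these, Cx3cl1 rose (14.6 to 22.5 FPKM) and 4 fell, namely Lcn2 (2.41 to 0.40 FPKM), Icam1 (0.41 to 0.13 FPKM), Csf1 (1.35 to 0.75 FPKM) and Relb (1.78 to 1.00 FPKM), with 1 and 4 also adjusted over the list alone. The median of that list, -0.27, lay at percentile 9.38.

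**Figure D1:**
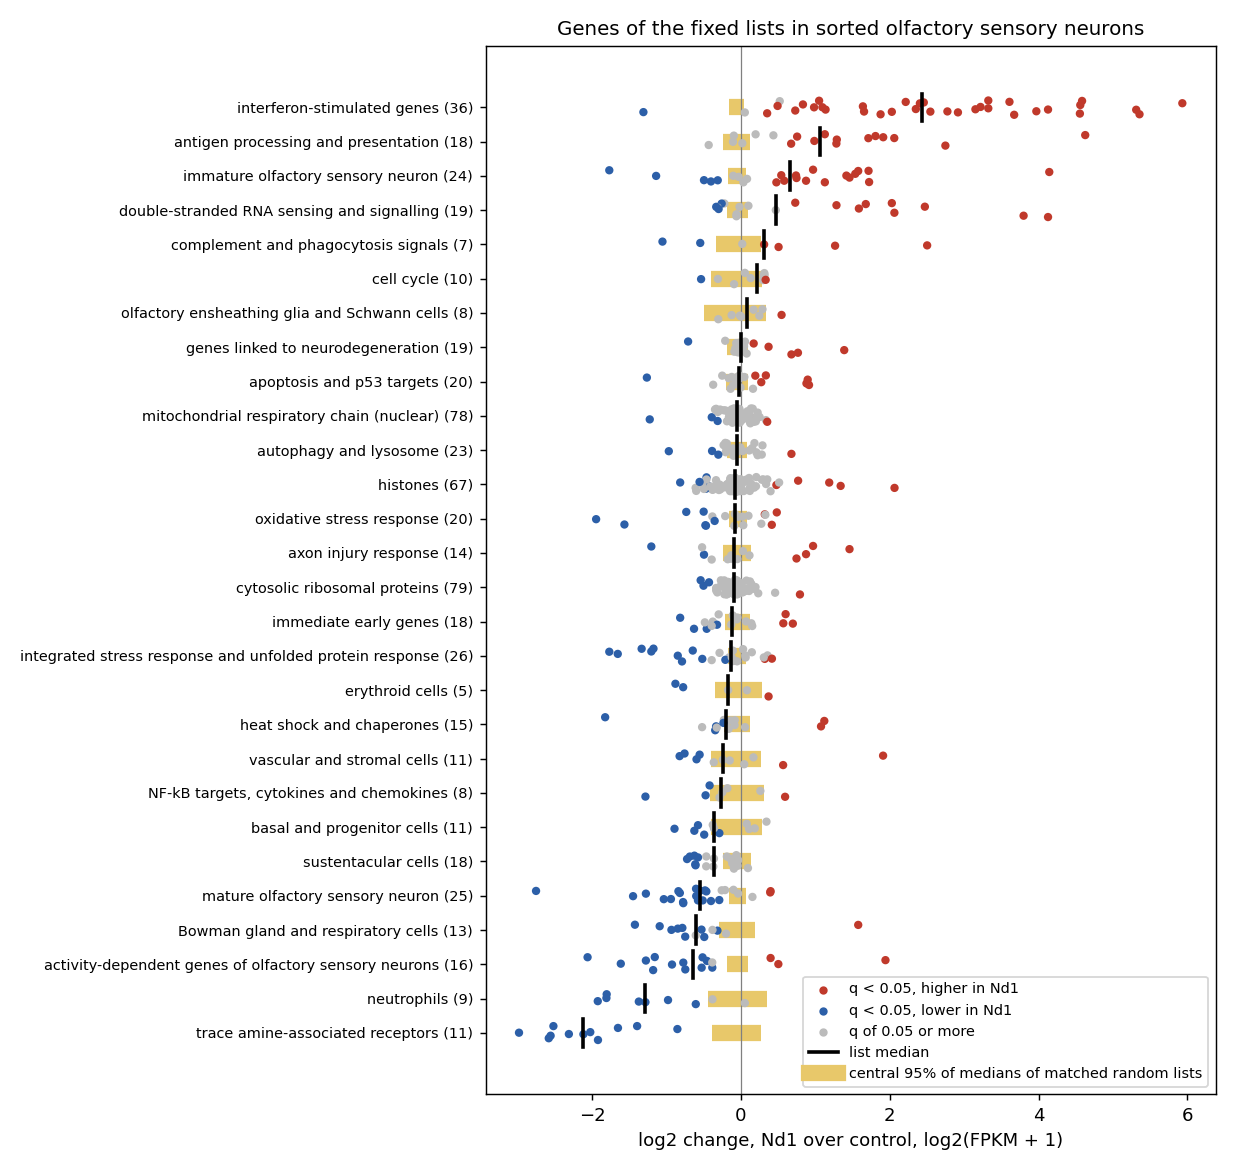
Change of each measured member of the fixed gene lists between Nd1 and control, as the difference of log2(FPKM + 1) of the authors' pooled group values (horizontal axis), with 1 list per line and the number of measured members in brackets. Points are genes coloured by the authors' q, black bars are list medians and yellow bars the central 95% of medians of 10000 matched random lists; interferon-stimulated genes lie farthest to the right (median 2.43) and trace amine-associated receptors farthest to the left (median -2.12).

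Odorant receptor genes, which encode the receptors that define each neuron's odour tuning, fell across the genome. Of 1016 tested loci 896 fell, 4 rose and 116 did not pass in the authors' deposited table, and over the 1014 distinct symbols tested 925 were lower and 4 higher when adjusted over the list alone. The median log2 ratio was -3.22, a 9.30-fold lower level, with quartiles at -4.56 and -2.08. On the log2(FPKM + 1) scale, over receptors with a mean of at least 0.5 FPKM, the median was -1.74. The summed FPKM of all 1084 receptor loci was 8621 in control and 1629.8 in Nd1. Of the receptors that fell, 27 were listed at 0 in Nd1 in the authors' deposited table. The 4 receptors that rose were Olfr1440 (16.9 to 43.8 FPKM), Olfr49 (9.77 to 16.0 FPKM), Olfr1367 (1.62 to 4.61 FPKM) and Olfr768 (1.19 to 2.34 FPKM). Receptor genes resemble each other closely, so reads shared between paralogs may be split in ways the table does not show. Trace amine-associated receptors, a second chemoreceptor family, fell in 13 of 14 tested loci, or 14 adjusted over the list alone, with a median log2 ratio of -3.77. Taar9 fell from 10.8 to 0.49 FPKM, Taar7a from 5.58 to 0.33, Taar7e from 3.17 to 0.10 and Taar7f from 3.82 to 0.18 FPKM. Only 6 of 326 vomeronasal receptor genes were tested, and Vmn2r2 (0.048 to 1.91 FPKM) and Vmn2r1 (0.038 to 0.93 FPKM) rose, also adjusted over the list alone.

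**Figure D2:**
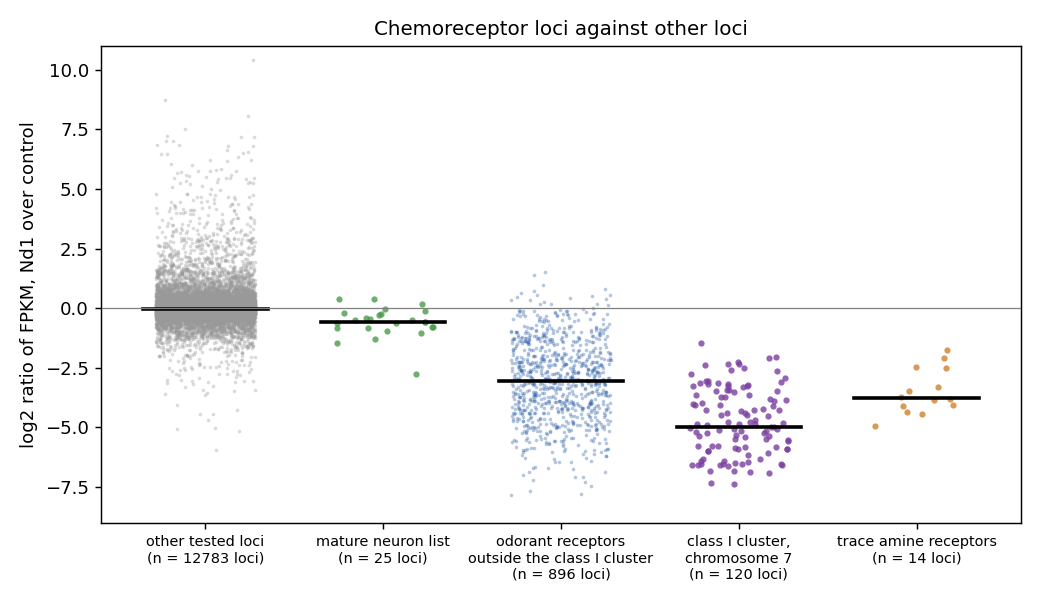
Log2 ratio of the authors' pooled FPKM, Nd1 over control, for chemoreceptor loci, for the mature neuron list and for all other tested loci with a mean of at least 0.5 FPKM. Each point is a locus and black bars are medians, which count loci listed at 0 in a group although these are not drawn; odorant receptors outside the class I cluster have a median of -3.07 and the mature neuron list a median of -0.56.

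Markers of mature olfactory sensory neurons fell, by less than the receptors did. Of 25 tested members of that list 18 fell and 2 rose in the authors' deposited table, with 18 and 2 also adjusted over the list alone. Omp, the olfactory marker protein whose locus carries the reporter and the tTA insertion (mm9 chromosome 7, 105270075 to 105327920), fell from 4087 to 605 FPKM, a log2 fold change of -2.755 in the authors' deposited table. The groups differ in their Omp alleles, since both Nd1 libraries carried tTA there and the control of replicate 1 did not. The cilia protein Stoml3 fell from 3425 to 1254 FPKM, the calcium-binding S100a5 from 3542 to 1461 and the phosphodiesterase Pde1c from 243 to 118 FPKM. After quantile normalization the falls of Stoml3 and S100a5 were smaller, at -0.57 in place of -1.45 and -0.52 in place of -1.28 on the log2(FPKM + 1) scale. Components of odour transduction were also lower, with Cnga2, a subunit of the cyclic nucleotide-gated channel, at 859.5 and 486 FPKM and the adenylate cyclase Adcy3 at 888 and 496 FPKM (q = 0.000198 for Cnga2, q listed as 0 for Adcy3, in the authors' deposited table). Gnal, the G protein alpha subunit of the pathway, stood at 1672 FPKM in control and 924 in Nd1, but the authors' test failed for it, so it carries no call. The 2 rises were those of Ncam2 (51.9 to 68.5 FPKM) and Calb2 (108 to 143 FPKM). The list median was -0.55 on the log2(FPKM + 1) scale, at percentile 0 of matched random lists.

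Markers of immature olfactory sensory neurons rose in 15 of 24 tested genes and fell in 5 in the authors' deposited table, with 15 and 5 also adjusted over the list alone. The G protein subunit Gng8 rose from 3.11 to 71.7 FPKM, the transcription factors Nhlh2 from 0.90 to 5.25 and Nhlh1 from 1.58 to 7.52, and the actin-binding Ablim1 from 0.57 to 3.20 FPKM. The 5 falls were those of Trib3 (14.5 to 3.55 FPKM), Cd24a (20.7 to 8.83 FPKM), Stmn4 (137 to 96.7 FPKM), Lhx2 (227 to 172 FPKM) and Ncam1 (246 to 198 FPKM). The median of 0.66 lay at percentile 100. Genes whose level depends on odour-evoked activity, in either direction, fell in 12 of 16 tested members and rose in 3 in the authors' deposited table, or 13 and 3 adjusted over the list alone, with a median of -0.64 at percentile 0, which is no measure of activity because the directions are mixed. Among them the axon guidance gene Sema7a fell from 104 to 24.3 FPKM and Lrrc3b from 135 to 43.5 FPKM. The rises were those of Mustn1 (0.97 to 6.58 FPKM), Efna5 (41.0 to 58.5 FPKM) and Calb2. Immediate early genes split, with 4 of 20 tested higher and 5 lower, or 4 and 6 adjusted over the list alone, and a median of -0.12 at percentile 19.2. Junb (18.6 to 30.8 FPKM), Egr4 (0.65 to 1.44 FPKM), Fosb (8.56 to 13.5 FPKM) and Arc (0.26 to 0.72 FPKM) rose, while Klf4 (1.82 to 0.82 FPKM), Dusp6 (3.99 to 1.83 FPKM), Fosl2 (0.35 to 0.18 FPKM), Ier2 (53.7 to 38.8 FPKM) and Dusp1 (55.7 to 44.4 FPKM) fell.

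**Figure D3:**
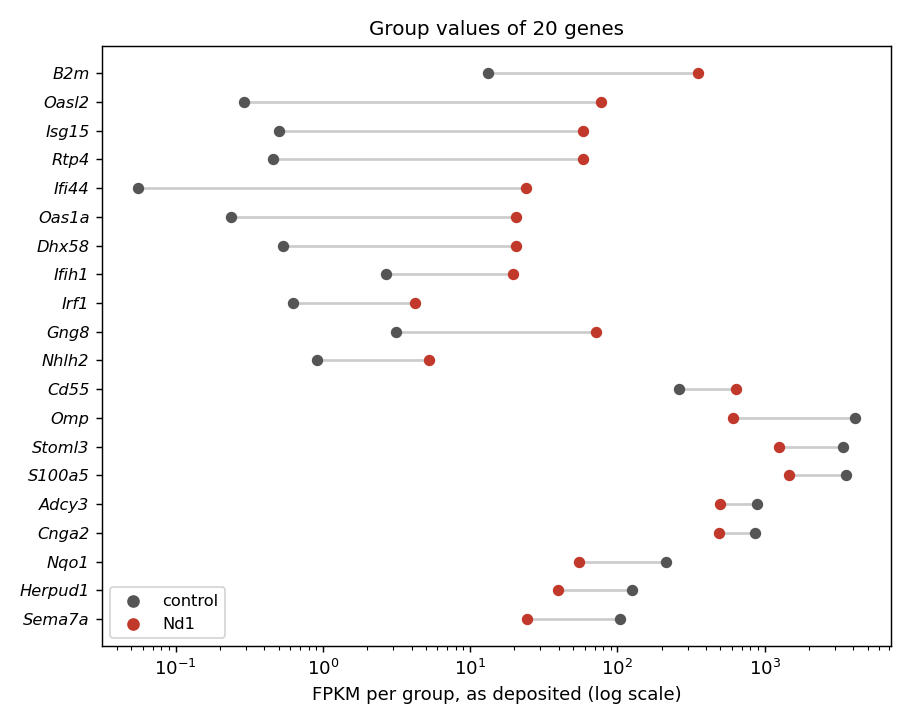
Pooled FPKM of 20 genes in control (grey) and Nd1 (red), as deposited by the authors, on a log axis and without error bars because the table gives 1 value per group. B2m moves from 13.3 to 352 FPKM and Omp from 4087 to 605 FPKM.

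Stress pathways did not rise as groups. Of 27 tested genes of the integrated stress and unfolded protein responses, 10 fell and 2 rose in the authors' deposited table, with 10 and 2 also adjusted over the list alone, and the median of -0.14 lay at percentile 6.75. Herpud1, an endoplasmic reticulum stress protein, fell from 126 to 39.3 FPKM, the phosphatase subunit Ppp1r15a from 84.8 to 33.0, Ddit3 (CHOP) from 55.9 to 23.7 and Trib3 from 14.5 to 3.55 FPKM. The rises were those of Slc7a11 (25.2 to 31.7 FPKM) and Edem1 (4.81 to 6.76 FPKM). Heat shock genes gave 4 falls and 2 rises among 15 tested, or 6 and 2 adjusted over the list alone (median -0.20, percentile 4.27). Hspa1a rose from 2.70 to 7.04 FPKM and its near copy Hspa1b from 2.70 to 6.80 FPKM, whereas the co-chaperone Bag3 fell from 5.80 to 0.92, Hsp90aa1 from 173 to 136, Hsph1 from 26.0 to 20.5 and Hspa4l from 57.9 to 49.1 FPKM. Of 20 oxidative stress genes 7 fell and 3 rose, or 8 and 3 adjusted over the list alone (median -0.085, percentile 27.6). Nqo1 fell from 214 to 54.9 FPKM, Hmox1 from 23.9 to 7.41, the metallothionein Mt1 from 435 to 261 and Prdx1 from 78.5 to 55.2 FPKM, and Slc7a11, Gclc (14.4 to 19.5 FPKM) and G6pdx (40.7 to 57.2 FPKM) rose.

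Apoptosis and p53 target genes gave 6 rises and 2 falls among 22 tested in the authors' deposited table, or 6 and 3 adjusted over the list alone, with a median of -0.019 at percentile 72.3. Among these, the BH3-only gene Hrk rose from 29.2 to 54.6 FPKM and the death ligand Tnfsf10 from 0.18 to 1.23 FPKM, while the cell cycle inhibitor Cdkn1a fell from 46.1 to 18.6 and Gsdmd from 0.47 to 0.16 FPKM. Axon injury genes gave 4 rises and 2 falls among 15, or 4 and 3 adjusted over the list alone (median -0.089, percentile 37.1). The rises were Sox11 (1.95 to 7.12 FPKM), Gap43 (12.2 to 24.9 FPKM), Tubb3 (247 to 453 FPKM) and Stmn2 (95.1 to 160.4 FPKM), all of which also stand in the immature neuron list, and the falls were Ddit3 and Stmn4. Genes linked to neurodegeneration gave 5 rises and 1 fall among 19 tested, with 5 and 1 also adjusted over the list alone (median 0.0047, percentile 81.1). The share of tested members called, in this list as in the apoptosis list, lay near the 34.4% of all tested loci. Mapt, which encodes tau, rose from 1.62 to 5.86 FPKM, Optn from 0.56 to 1.50, Park2 from 2.56 to 5.05 and Atxn2 from 25.1 to 28.4 FPKM, and Apoe fell from 20.9 to 12.4 FPKM. Autophagy and lysosome genes gave 1 rise, of Optn, and 3 falls among 24 tested, or 1 and 2 adjusted over the list alone (median -0.058, percentile 48.0), the falls being those of Tfeb (2.495 to 0.79 FPKM), Map1lc3a (73.3 to 55.8 FPKM) and Npc1 (22.5 to 18.0 FPKM). Complement and phagocytosis genes gave 4 rises and 3 falls among 8, with 4 and 3 also adjusted over the list alone (median 0.31, percentile 98.6). Here the complement inhibitors Cd55 (263 to 635 FPKM) and Serping1 (3.58 to 24.96 FPKM), with Mfge8 (25.3 to 36.4 FPKM) and Cd47 (56.8 to 70.8 FPKM), rose, and the falls included Cd59a (6.96 to 2.83 FPKM) and C2 (1.52 to 0.72 FPKM).

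Among markers of the other cell types that a sort could carry few rose, and most fell, did not pass or were not tested. Neutrophil genes fell in 8 of 10 tested in the authors' deposited table, or 9 adjusted over the list alone (median -1.28, percentile 0.04), Ngp from 5.59 to 0.89 FPKM, Camp from 2.34 to 0.29, Retnlg from 1.17 to 0.098 and Lcn2 from 2.41 to 0.40 FPKM. Gland and respiratory genes fell in 9 of 13, or 11 adjusted over the list alone (median -0.61, percentile 0.03), among them Bpifa1 (184 to 68.1 FPKM), Krt7 (4.79 to 2.03 FPKM), Reg3g (16.3 to 7.14 FPKM) and Bpifb4 (3.99 to 1.90 FPKM), whereas Obp1a rose. Sustentacular cell genes fell in 7 of 19 tested in the authors' deposited table, or 8 adjusted over the list alone. Krt18 went from 15.5 to 8.97 FPKM, Gstm2 from 5.91 to 3.29, Krt8 from 6.48 to 3.90 and Sox2 from 3.12 to 1.76 FPKM. The other 12 did not pass. Among these were Sult1d1 (254 and 234 FPKM), Cyp2g1 (15.8 and 15.3 FPKM) and Cyp2a4 (7.53 and 7.17 FPKM), named here after their values were seen. The median of that list, -0.37, lay at percentile 0.23, but at 1.07 after quantile normalization and at 21.7 among the upper 50% of expressed genes. Basal and progenitor genes fell in 6 of 12 tested, or 7 adjusted over the list alone (median -0.36, percentile 3.32), including Krt5 (8.03 to 3.86 FPKM), Trp63 (1.85 to 0.85 FPKM) and Krt14 (2.29 to 1.33 FPKM). With receptor loci left out of the background that percentile was 0.27. Cell cycle genes gave 1 rise, of Kif11 (0.39 to 0.76 FPKM), and 1 fall, of Rrm2 (0.86 to 0.29 FPKM), among 15 tested, with 1 and 1 also adjusted over the list alone (median 0.21, percentile 95.02).

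Macrophage and microglia genes were tested in 9 of 25 cases, and 4 fell, or 5 adjusted over the list alone, namely Ptprc (0.49 to 0.048 FPKM), Mpeg1 (0.54 to 0.24 FPKM), Spp1 (4.03 to 1.85 FPKM) and Apoe. Of 5 tested lymphocyte genes only Gzma, a granzyme, rose (0.26 to 5.65 FPKM), with a log2 fold change of 4.46 (q = 9.85e-12) in the authors' deposited table, and it was the single call adjusted over the list alone. Erythroid genes gave 2 falls, of Hbb-b1 (22.7 to 11.9 FPKM) and Hba-a2 (40.5 to 23.2 FPKM), and 1 rise among 5 tested, with the same counts adjusted over the list alone (median -0.17, percentile 17.5). Vascular and stromal genes gave 4 falls and 2 rises among 12, with 4 and 2 also adjusted over the list alone (median -0.24, percentile 11.5). Pdgfra (1.03 to 0.15 FPKM), Pdgfrb (0.88 to 0.25 FPKM), Rgs5 (7.65 to 4.12 FPKM) and Vwf (5.45 to 3.39 FPKM) fell, while the endothelial adhesion genes Esam (0.17 to 3.38 FPKM) and Pecam1 (1.49 to 2.68 FPKM) rose. Of 9 tested genes of ensheathing glia and Schwann cells only Mbp rose (8.02 to 12.2 FPKM), also adjusted over the list alone (median 0.088, percentile 82.4).

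The large housekeeping families stayed near the median of all loci. Of 79 cytosolic ribosomal protein genes tested, Rps4y2 rose (6.26 to 11.6 FPKM) and Rps3a (47.3 to 32.2 FPKM), Rps2 (19.0 to 13.1 FPKM) and Rps15a (8.78 to 6.26 FPKM) fell in the authors' deposited table, or 1 and 2 adjusted over the list alone (median -0.095, percentile 5.93). Of 78 nuclear genes of the mitochondrial respiratory chain, Ndufs4 (35.2 to 45.3 FPKM) and Atp5f1 (79.6 to 88.9 FPKM) rose and Cox8b (9.92 to 3.67 FPKM), Ndufv3 (211 to 161 FPKM) and Ndufv1 (56.2 to 45.0 FPKM) fell, or 0 and 2 adjusted over the list alone (median -0.051, percentile 46.9). Of 71 histone genes 5 rose and 5 fell, or 4 and 2 adjusted over the list alone (median -0.078, percentile 39.4), and the rises were H1fx (1.16 to 8.05 FPKM), Hist3h2ba (5.66 to 15.9 FPKM), Hist2h4 (8.50 to 20.6 FPKM), Hist3h2bb-ps and H1f0, the falls H1foo, Hist1h2bf (3.79 to 1.72 FPKM), Hist1h2ac, Hist1h2bc and the joined locus of Hist3h2a and Trim17.

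Across the 32 lists and families, 29 had at least 5 measured members, and the medians of 11 lay outside the central 99% of matched random lists, 4 above and 7 below. These percentiles describe the pooled values of these libraries and are not a test across replicates. The authors' q values rest on 2 libraries per group that differ in age and, in the controls, in genotype. A comparison of 212 with 87 days was not possible, because the pooled values do not separate the ages.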

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

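The tests in this part were chosen after the data had been seen. Signals lie in loci that no gene comparison of the report could use, because the table gives them no symbol or because the authors' test failed. Of these, 11 reached at least 1 FPKM in Nd1 and at least 8 times the control value, 7 without a symbol and 4 with a failed test.

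Among loci without a symbol, 3 neighbours on mm9 chromosome 14 stand out. In the authors' deposited table the locus at 27512760 to 27543988 went from 0.14 to 16.0 FPKM (q listed as 0), the one at 27584215 to 27586944 from 0.066 to 6.59 FPKM (q = 0.00418) and the one at 27685519 to 27704889 from 0.076 to 6.10 FPKM (q = 2.57e-11). The genes on either side, Pde12 (12.1 and 10.9 FPKM) and Asb14 (1.47 and 1.58 FPKM), did not pass. Farther off, 1 of the 2 entries of Fam116a rose from 0.16 to 1.25 FPKM (q = 0.0308 in the authors' deposited table) and the other (8.53 and 8.31 FPKM) did not pass. Another locus without a symbol, on chromosome 12 from 114493110 to 117248164, was listed at 0 in control and at 1.55 FPKM in Nd1. The remaining 3 were on chromosome 12 from 72678952 to 72687808 (0.028 to 1.07 FPKM), on chromosome 13 from 47081816 to 47104082 (0.039 to 1.89 FPKM) and on chromosome 3 from 106737300 to 106901319 (0.055 to 2.36 FPKM).

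Of the loci whose test failed, Irf7, the master regulator of type I interferon genes, stood at 1.23 FPKM in control and 55.3 FPKM in Nd1. Ildr2 stood at 0.67 and 8.89 FPKM, 1190007F08Rik at 0.46 and 7.99 FPKM, and the joined locus of 1600029I14Rik and Txndc6 at 0.50 and 5.04 FPKM. Over all failed loci, 25 differed by at least 2-fold with 1 FPKM or more in a group, so the counts of calls omit some large differences.

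The height of Irf7 goes with the rise of the interferon-stimulated genes, for which immune cells carried through the sort for neurons were weighed as a technical source. The summed FPKM of the neutrophil list (15 loci, 2 of which also stand in other lists) was 38.0 in control and 10.5 in Nd1, a ratio of 0.28, and 8 of its 10 tested members fell while 0 rose, which argues against more neutrophils in the Nd1 sort. The macrophage list went from 36.2 to 25.2 FPKM, but without Apoe and Spp1, which other cells express too, from 11.21 to 10.96 FPKM, a ratio of 0.98, with 2 of 7 tested members lower and 0 higher. The 16 of the 25 loci of that list that were not tested were low in both groups. The highest of them were Itgam at 0.25 FPKM in control and C1qa at 0.24 FPKM in Nd1. The list thus gives no sign of more macrophages in the Nd1 sort. Macrophages as a part source stay open only because values this near 0 cannot exclude a small share. The split of the lists, the omission of Apoe and Spp1 and a bound of 0.5 on the ratio were set after these sums had been seen, in place of a bound of 1 on both lists together, under which the macrophages too had counted as excluded. The lymphocyte list is less clear, with sums of 11.2 and 16.9 FPKM, a ratio of 1.51. Most of the control sum was Cd247 (8.51 and 9.05 FPKM), and most of the gain was Gzma, which alone went from 0.26 to 5.65 FPKM. The ratio is therefore no measure of the list as a whole. Outside that list, Cd69 (0.031 to 4.51 FPKM) and the MHC class II gene H2-Ab1 (1.53 to 4.52 FPKM) also rose. By contrast H2-Aa (1.01 and 0.49 FPKM), H2-Eb1 (0.36 and 0.34 FPKM), Cd74 (2.65 and 2.42 FPKM) and Ciita (0.91 and 0.93 FPKM) did not pass. The other 4 tested lymphocyte genes did not pass either, and Ptprc, which leukocytes share, fell from 0.49 to 0.048 FPKM. The 16 of the 21 loci of the lymphocyte list that were not tested were low in both groups. The highest was Cd8b1 (0.28 and 0.26 FPKM), and Cd3e stood at 0 and 0.025 FPKM. The list beyond Gzma thus gives no sign of more lymphocytes, but with the rises of Gzma and Cd69 lymphocytes as a part source stay open. Whether the sorted cells may themselves make interferon stays open too, since the highest value of the 17 interferon genes in Nd1 was 0.42 FPKM (Ifna4, listed at 0 in control) and 13 were listed at 0 in both groups.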

How the results depend on the processing

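No paired analysis was possible because the table holds 1 pooled value per group, which carries no replicate number. For the same reason the planned fits without the trend, with a replicate block, without each replicate, on raw counts or with an estimated correlation, the overlap of another test with the authors' calls, and all alternatives of the age comparison were not run, so nothing here shows whether a single library decides a value. The settings with a q of 0.01, without odorant receptors, with 1 locus per symbol, and with changed list membership, list filter or receptor-free background were chosen after seeing the data. The 5102 calls of the authors became between 3649 (mean of at least 2 FPKM) and 4977 under the other filters and thresholds, always within 1.5 times. Quantile and median-ratio scaling moved the median locus by 0.055 and 0.061 (log2) and quantile normalization turned the direction of 3 called loci. Leaving out odorant receptors moved the share of higher calls from 44.0% to 53.4%. Of the 123 named loci, quantile normalization turned the sign of 0 and moved 2, Stoml3 and S100a5, by over 1.5 times. Of the 117 above 0 in both groups, pseudocounts of 0.1, 0.5 and 1 moved 15, 34 and 42 by over 1.5 times from the plain ratio and turned the sign of 0. Rasgrf1 went from 10.41 to 6.61, 4.43 and 3.51 and Gm10081 from -5.16 to -3.65, -2.05 and -1.40, and neither kept its first rank under any of the 3. The receptor median over loci of at least 0.5 FPKM was -3.25 as a plain ratio, -2.98, -2.21 and -1.74 with pseudocounts of 0.1, 0.5 and 1, and -1.63 after quantile normalization. The number of lists apart from matched lists was 11, and 10 to 12 under the alternatives except among the upper 50% of expressed genes, where it was 7. Only 20 lists kept 5 members there, so the neutrophil and trace amine receptor lists were not evaluated, while the dsRNA sensing and sustentacular lists no longer stood apart. In that setting the median of the dsRNA sensing list was -0.019 in place of 0.47, and the cause was not tested beyond the loss of its less expressed members. The unknown depth limits the precision of low values.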

Other observations

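The tests of explanations in this part were chosen after the data had been seen, as were its genes other than Omp, Stoml3 and Nqo1, for their size of change or their known role, while the receptor families, pseudocounts and scalings were planned. In the authors' deposited table the neighbouring homeobox genes Dlx5 (1.97 to 24.9 FPKM) and Dlx6 (3.08 to 23.4 FPKM) and the antisense transcript Dlx6as1 (0.94 to 9.84 FPKM) on chromosome 6 rose together. Dlx6 and Dlx6as1 share a locus in the table, so how their reads were parted is uncertain. The intermediate filament gene Prph rose from 21.5 to 217 FPKM, the microtubule gene Mtap2 from 8.54 to 52.4, the tubulin-binding Tppp3 from 57.3 to 335 and the secreted regulator Nov from 1.89 to 139 FPKM. Of regulators tied to odorant receptor expression, Emx2 (39.5 to 66.7 FPKM) and Ebf1 (108 to 166 FPKM) rose and Lhx2 (227 to 172 FPKM) and Atf5 (1404 to 779.6 FPKM) fell, while the receptor transport genes Rtp1 (566 and 473 FPKM) and Rtp2 (386 and 333 FPKM) did not pass.

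The major urinary protein genes Mup4 (0.055 to 4.10 FPKM) and Mup5 (0.070 to 1.33 FPKM) and the lipocalin Lcn13 (1.17 to 2.96 FPKM) rose in the authors' deposited table. Of the interferon receptors, Ifngr1 rose from 2.05 to 8.46 FPKM, and Ifnar1 (21.4 and 22.02 FPKM), Ifnar2 (11.96 and 12.1 FPKM) and Ifngr2 (8.80 and 9.17 FPKM) did not pass. Xist stood at 38.3 and 61.6 FPKM (q = 0.013 in the authors' deposited table), and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty did not pass.

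The fall of the odorant receptors, with a median log2 ratio of -3.22, was set against 2 technical sources. Scaling between the groups would move all loci alike, but the median over tested loci outside the receptor families was -0.043. A lower share of mature neurons in the sort would lower their other transcripts as far, if the cells in their place lacked them. The 24 measured members of the mature neuron list other than Omp had a median of -0.54, the lowest being Stoml3 at -1.45. The 4 members whose test failed are not among these 24. Of them Ric8b (796 and 273 FPKM) had a somewhat lower ratio than Stoml3, and Gnal, Gnb1 and Ebf2 had higher ones. Omp, at -2.755, was left out because its alleles differ between the groups by genotype, which may itself lower it. With pseudocounts of 0.1, 0.5 and 1 and under both scalings the receptor median shrank to as little as -1.63, yet 0 of the 24 lay at or below it in any of these, while Omp did at 0.5, at 1 and under both scalings. These values argue against scaling as the whole source, and against replacement of mature neurons by cells that lack the list's transcripts. They cannot decide on a shift toward younger neurons, which may already carry part of these transcripts. Lhx2 stands in both the mature and the immature neuron list, and of 24 tested genes of the immature list 15 rose and 5 fell.

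The fall was not even across the receptor repertoire. The 120 tested loci of the cluster on mm9 chromosome 7 from 109625287 to 112517831, which holds the class I receptors, had a median log2 ratio of -4.98, and 119 of them fell, against a median of -3.07 and 777 of 896 for all other receptors. The cluster did not start lower, with a median control value of 5.77 FPKM against 4.19 for the other receptors. A different starting level as the source is argued against, because the cluster's median lay at percentile 0 of 10000 sets of other receptors matched on control FPKM, whose own medians had a central range of -3.41 to -2.67. A candidate explanation is a greater loss of dorsal neurons, since class I receptors and trace amine-associated receptors (median -3.77) are expressed mainly there. In the authors' deposited table the dorsal zone gene Nqo1 had a log2 fold change of -1.96, but Acsm4, another such gene, one of 0.019, so the markers part and the explanation stays open. At the other end, of the 56 tested receptors between 128426970 and 129648184 of mm9 chromosome 10, 30.4% did not fall, against 10.7% of all other receptors. The median log2 ratio of these 56 was still -1.81. This block was chosen after the data had been seen and was not matched on control FPKM, so its starting level may play a part.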
